A study of Ricinus communis with 12 samples.

How the data were processed

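RNA of the embryo and of the endosperm of mature castor seeds (Ricinus communis, cultivar Baker 296, plants grown in a greenhouse) was measured by mRNA sequencing in 12 libraries, 6 per tissue. Per the labels' protocols, total RNA was extracted with a hot borate method and made into Illumina TruSeq-type libraries that were sequenced as paired reads on a NextSeq instrument. Per the submitters' processing notes, Trimmomatic, Salmon and DESeq2 were used. Their versions, their settings, the transcript set and the genome build are not given in the sources used here. Salmon estimates how many reads each transcript produced and shares reads among similar transcripts, so values of transcripts of the same gene, or of near-identical genes, are less certain than their totals show.

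The deposited estimated counts are whole numbers for 29707 RefSeq transcripts, of which 27902 have protein-coding and 1805 have noncoding accessions, and cover 10 libraries. The deposited normalized values are a signal for all 12 libraries, made by the authors by dividing each library's counts by 1 size factor. In the 10 libraries shared by both tables the ratio to the counts was constant within a largest relative deviation of 7.0e-10. The size factors equalled median-of-ratios factors recomputed over the 12 libraries, with a largest difference of 3.0e-08%. In the libraries numbered 5 of both tissues, 100% of the normalized values were whole multiples of 1 step within a tolerance of 0.01 reads, and the whole reads recovered in this way were used for these 2 libraries.

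Transcript accessions were matched, ignoring version numbers, to the assembly ASM1957865v1 of castor, which was used only for gene symbols, short names and the order of neighbouring genes. In all, 20902 transcripts (70.4%) matched 16131 genes, and they held 84.1% of the counts. Before the data were examined, 24 gene lists had been defined by product names. The reference gave no product names, so 0 of the 24 lists reached the minimum of 5 matched genes, and the planned tests of lists and of their shares of the counts were not run. In their place, the 72 genes with a short name were sorted into lists after the names, but before any values, had been seen. Of these, 11 genes had a matched transcript, and the largest list held 4 such genes. A gene without a match may still have reads under an unmatched accession.

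Endosperm was compared with embryo per transcript with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by tissue and Benjamini-Hochberg adjustment at 0.05. The plan named 12 libraries. After the files had been seen, the test was run instead on the 10 libraries of the count table, 5 per tissue, because these counts needed no recovery, and the fit on all 12 became an alternative. Log2 fold changes are endosperm minus embryo, and their standard errors are the fold change divided by the square root of F. Levels are TMM-scaled CPM, mean ± SD over 5 libraries, unless stated otherwise. The labels do not say that libraries came from separate plants or seeds, so p-values measure only the spread between these samples. No pair of replicates agreed within sampling noise, the lowest chi-square per degree of freedom being 20.6.

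Shares and breadth were compared over 12 libraries by two-sided exact permutation tests of all 924 relabellings, with Benjamini-Hochberg adjustment over 9 measures. For breadth, every library was thinned at random to 2675474 reads, the depth of the shallowest. Transcript usage within genes was tested with diffSpliceDGE of edgeR in genes with at least 2 tested transcripts. Other tools were limma 3.58.1, DESeq2 1.42.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 in Python 3.11.15.

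The edgeR test was tested on simulated data of the 16605 tested transcripts, in 5 against 5 libraries. Depths and dispersions were the real ones, and each transcript had 1 mean taken over both tissues. The changed transcripts were drawn from those with a mean of at least 1 CPM, so recovery below that level was not measured. The edgeR test recovered 1 of 50 transcripts changed by a log2 fold of 0.5, 2 of 50 at 1, 25 of 50 at 2 and 27 of 50 at 3, with 5 false calls among 16405 unchanged transcripts. With so few changed transcripts the adjustment is stricter than in the real comparison. The usage test recovered 29 of 100 changed genes of 1949, with 5 false calls.

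Transcripts to be named were fixed before the data were examined as members of the product-name lists and the largest changes, or at most 2 identifiers per direction where names could not be matched. With the product names missing, the text names every tested transcript with a short name, the 2 largest fold changes per direction among called transcripts with at least 10 CPM and no overlap, and a few others marked as chosen after their values were seen. A fold against a tissue with 0 reads was computed against 3 counts over the whole group and is a lower bound that covers counting error only. Alternatives covered scaling, filters, tools, thresholds, the replicate number as a block, the normalized table, all 12 libraries, sums per gene and leaving out each library.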

Results

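Castor seeds store an oil rich in ricinoleic acid, most of it in the endosperm, which surrounds a thin embryo. The transcriptomes of both tissues were measured in mature seeds, 6 libraries each, to ask how transcripts differ between tissues that differ in ricinoleic acid accumulation. The embryo libraries held 10415612 to 12968343 assigned reads. The endosperm libraries 1, 2, 3, 4 and 6 held 6920870 to 8871518, and endosperm library 5 held 2675474. Every embryo library was therefore deeper than every endosperm library.

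The tissues separated along the leading axis of variation. Embryo libraries resembled each other closely, with Pearson correlations across transcripts of 0.923 to 0.963 (median 0.944 over 15 pairs, log2(CPM + 1)). Endosperm libraries were more varied, at 0.781 to 0.927 (median 0.883 over 15 pairs), and libraries of different tissues correlated at 0.753 to 0.849 (median 0.793 over 36 pairs). Transcripts are not independent replicates, so these values describe the libraries and carry no test. Endosperm library 4 correlated with the embryo libraries at a median of 0.838, against 0.786 for endosperm libraries 1, 2, 3 and 6. Endosperm library 5 correlated with the other endosperm libraries at a median of 0.796, against 0.891 among those others, and with the embryo libraries at 0.807, the only library nearer to the other tissue by this measure.

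**Figure D1:**
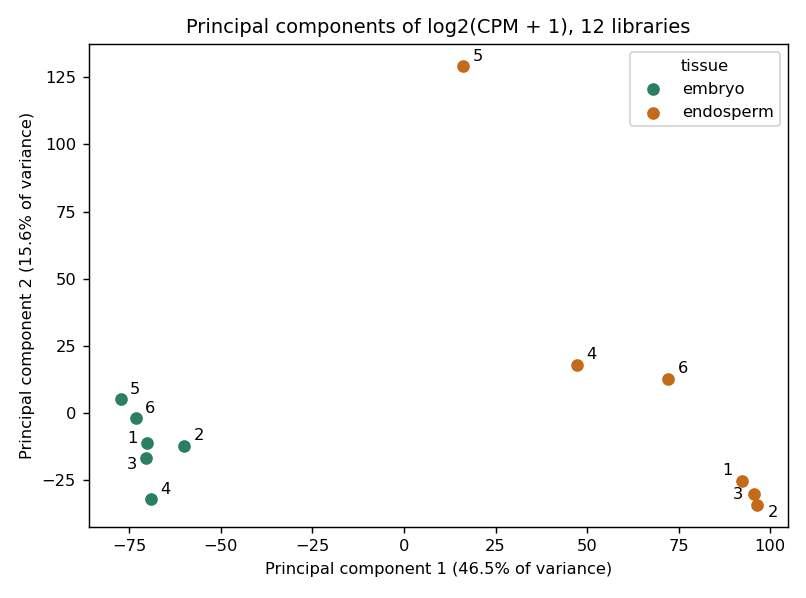
Principal components of log2(CPM + 1) of the tested transcripts in 12 libraries, with points coloured by tissue and numbered as in the labels. Component 1 (46.5% of variance) places all 6 embryo libraries on the left and all 6 endosperm libraries on the right, and component 2 (15.6%) sets endosperm library 5 apart.

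Embryo and endosperm differed in a large part of their transcripts, about equally in both directions. Of 16605 tested transcripts, 3267 were higher in endosperm and 3346 higher in embryo, together 39.8% (edgeR quasi-likelihood test, adjusted p at most 0.05, n = 5 per tissue). The differences were often large. Among the called transcripts, 2415 were at least 2-fold higher in endosperm and 2124 in embryo, and at a log2 fold change of 3 or more the numbers were 391 and 281. The median size of a called difference was 1.43 on the log2 scale for transcripts higher in endosperm and 1.21 for those higher in embryo. Of the 10111 tested transcripts with at least 10 CPM in the higher tissue, called or not, 41.4% had endosperm and embryo values that did not overlap (n = 5 each), where chance gives 0.794%. The balance of directions rests on the scaling. With library totals alone, which lowered the median log2 fold change of all transcripts to -0.21, 2536 transcripts were higher in endosperm and 4049 in embryo, and with upper quartile scaling, which raised it to 0.10, the numbers were 3778 and 2883.

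**Figure D2:**
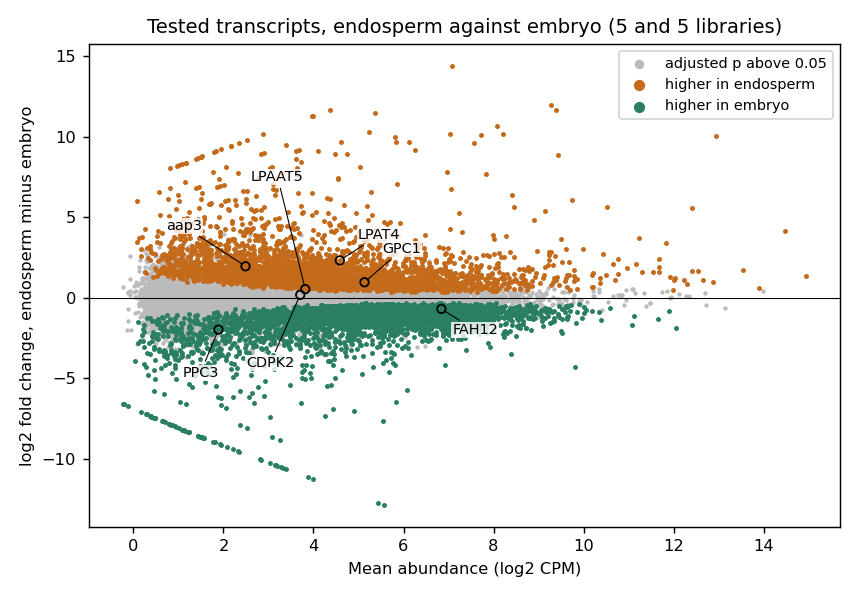
Log2 fold change (endosperm minus embryo) against mean abundance (log2 CPM) of the 16605 tested transcripts, coloured where adjusted p is at most 0.05 by edgeR's quasi-likelihood test on 5 and 5 libraries. Black circles mark the 7 transcripts with a short gene name, of which LPAT4 lies at 2.31 and FAH12 at -0.70, and the oblique lines of points at both edges are transcripts with no or almost no reads in the other tissue.

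FAH12 is the oleate hydroxylase that makes ricinoleic acid. In mature seeds, the only stage measured, its transcript was present in both tissues and was not higher in endosperm. Its level was 142 ± 32.6 CPM in embryo and 87.2 ± 23.4 CPM in endosperm (SD, n = 5 each), a log2 fold change of -0.70 ± 0.23 (SE). All 5 endosperm values lay below the embryo mean, though the ranges of the tissues overlapped. The difference passed the test at an adjusted p of 0.0326 (edgeR). With upper quartile scaling it was -0.58 (edgeR, adjusted p = 0.0703). The call also ended without embryo library 1, 2 or 3 (edgeR, adjusted p = 0.0668, 0.0504 and 0.0777) and without endosperm library 3 or 6 (edgeR, adjusted p = 0.0633 and 0.0617), while the sign held throughout.

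Both tested genes of triacylglycerol assembly, LPAT4 and LPAAT5, were higher in endosperm. LPAT4, named as a lysophosphatidic acid acyltransferase, an enzyme class that adds an acyl group on the path to storage oil, was 8.0 ± 3.22 CPM in embryo and 39.8 ± 13.3 CPM in endosperm (SD, n = 5 each). It was 4.97-fold higher in endosperm, a log2 fold change of 2.31 ± 0.32 (SE; edgeR, adjusted p = 0.000315), with all 5 endosperm values above the embryo mean. LPAAT5 of the same enzyme class rose less, from 11.4 ± 1.72 CPM in embryo to 16.4 ± 2.01 CPM in endosperm (SD, n = 5 each), a log2 fold change of 0.53 ± 0.18 (SE; edgeR, adjusted p = 0.0347), again in 5 of 5 endosperm libraries. That call ended with library totals alone (0.34, edgeR, adjusted p = 0.160), without a filter on low counts (0.53, edgeR, adjusted p = 0.0524), and without any 1 of embryo libraries 1, 3, 4 and 6 or endosperm libraries 1, 2 and 3 (edgeR, adjusted p = 0.0542 to 0.0897). Of the 4 matched genes of this list, LPATB and PDAT1-1 were too low to test, with 27 reads each in all 12 libraries. All LPATB reads were in embryo libraries, and so were the PDAT1-1 reads apart from 0.374 CPM in endosperm library 5. DGAT1, DGAT2, LPAT, LPAT2, PDAT1-2, PDAT2 and FAD2 were not analysed here.

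Among the other genes with a short name, GPC1 was 23.8 ± 5.20 CPM in embryo and 46.1 ± 14.6 CPM in endosperm (SD, n = 5 each), a log2 fold change of 0.95 ± 0.24 (SE; edgeR, adjusted p = 0.00932), and all 5 endosperm values lay above the embryo mean. The amino acid permease aap3 was 2.24 ± 1.14 CPM in embryo and 8.66 ± 6.24 CPM in endosperm (SD, n = 5 each), a log2 fold change of 1.95 ± 0.55 (SE; edgeR, adjusted p = 0.0151). Its highest value, 19.3 CPM before scaling, was in endosperm library 4, the library nearest to the embryo libraries among the 5 compared. PPC3, a phosphoenolpyruvate carboxylase, did not differ by the test, with 5.50 ± 4.22 CPM in embryo and 1.40 ± 1.28 CPM in endosperm (SD, n = 5 each) and a log2 fold change of -1.99 ± 1.05 (SE; edgeR, adjusted p = 0.160). In endosperm library 5 it stood at 31.0 CPM, and over all 12 libraries its log2 fold change was -0.16. The calcium-dependent protein kinase CDPK2 was at 12.1 ± 6.43 CPM in embryo and 13.6 ± 5.98 CPM in endosperm (SD, n = 5 each; log2 fold change 0.17 ± 0.40, SE; edgeR, adjusted p = 0.761), and the sign of this difference turned with library totals alone (-0.043) and without endosperm library 4 (-0.079). RcWRI1, a regulator of seed oil synthesis, had 43 reads and the sugar carrier HEX6 had 16 reads in all 12 libraries, so neither was tested. All reads of RcWRI1 were in endosperm libraries 4 and 5 (2.93 and 6.35 CPM), the 2 endosperm libraries nearest to the embryo libraries, although no embryo library had a read of it.

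**Figure D3:**
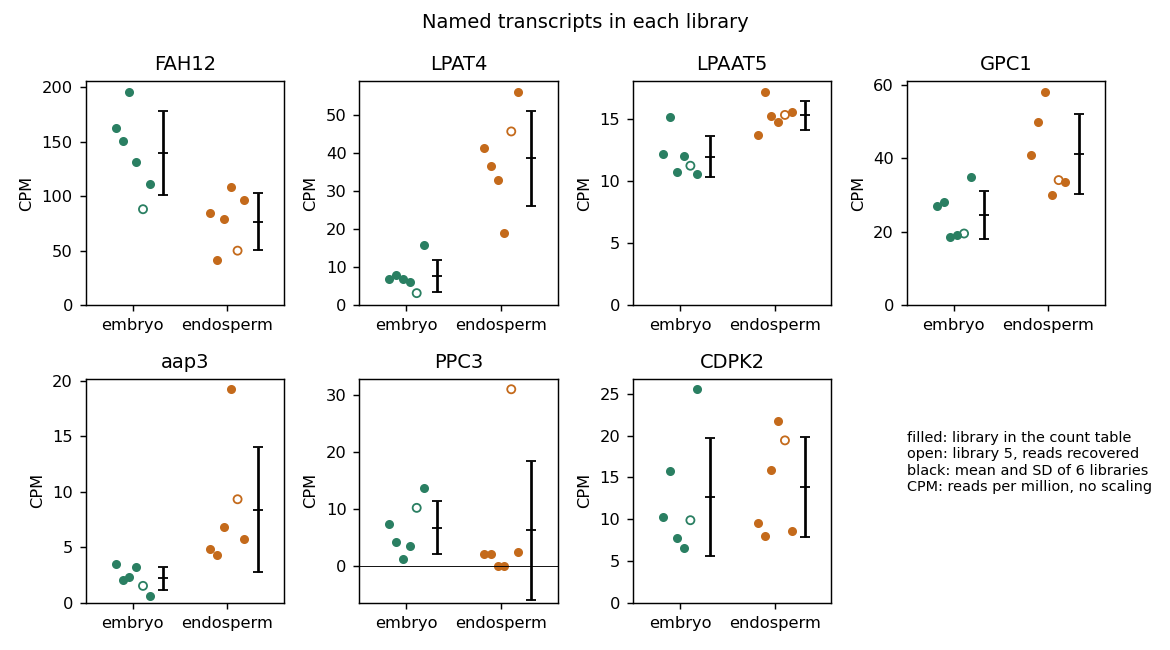
CPM before TMM scaling of the 7 tested transcripts with a short name in each of 12 libraries; filled points are the 10 libraries compared, open points the libraries numbered 5, and black bars the mean and SD of 6 libraries. LPAT4 is higher in every endosperm library than in every embryo library, FAH12 overlaps between the tissues once the libraries numbered 5 are included, and the PPC3 value of endosperm library 5 (31.0 CPM) and the aap3 value of endosperm library 4 (19.3 CPM) stand apart.

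Some transcripts were read in a single tissue. At 10 CPM or more in one tissue and 0 reads in the 5 compared libraries of the other, 6 transcripts were found in endosperm and 13 in embryo. Of the 13, 6 belonged to genes with another transcript that was read in endosperm, and of the 6, 1 belonged to a gene with another transcript read in embryo. In the libraries numbered 5 as well, 4 of the 6 and 9 of the 13 had 0 reads in the other tissue. The floor that 3 counts over the group allow was 0.0512 CPM in embryo and 0.0765 CPM in endosperm. XM_002536170, not matched to a gene, was 272 ± 254 CPM in endosperm (SD, n = 5), ranging from 50.9 to 592 CPM before scaling, which was at least 5318-fold higher than in embryo (edgeR, adjusted p = 0.000430). Embryo library 5, outside that comparison, held 1 read of it. LOC8273267 reached 1239 ± 1124 CPM in endosperm against 0.296 ± 0.234 CPM in embryo (SD, n = 5 each; 19 embryo reads), a log2 fold change of 11.94 ± 1.04 (SE; edgeR, adjusted p = 2.68e-05). In the other direction LOC8274244 was 94.6 ± 31.4 CPM in embryo (SD, n = 5), at least 1236-fold higher than in endosperm (edgeR, adjusted p = 2.80e-05). XM_002530982 was 85.6 ± 16.5 CPM in embryo (SD, n = 5), at least 1118-fold higher (edgeR, adjusted p = 6.50e-06), and neither had a read in any of the 6 endosperm libraries.

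The endosperm transcriptome was more concentrated in few transcripts than that of the embryo. The 20 most abundant transcripts of each library held 23.7% ± 3.52 of the reads in endosperm and 14.2% ± 1.26 in embryo (SD, n = 6 each), a difference of 9.58 percentage points (two-sided exact permutation test, p = 0.00216, the smallest it can give, adjusted p = 0.00487 over 9 measures). Every endosperm library, from 17.4% in library 5 upward, lay above every embryo library, of which the highest held 15.9%. At equal depth, 286 ± 117 transcripts accounted for 50% of the reads in endosperm against 594 ± 63.5 in embryo (SD, n = 6 each; exact permutation test, p = 0.00216, adjusted p = 0.00487). Transcripts with at least 1 read at that depth numbered 18204 ± 337 in endosperm and 18711 ± 315 in embryo (SD, n = 6 each; exact permutation test, p = 0.0238, adjusted p = 0.0357), a difference that did not pass without endosperm library 5 (exact permutation test, adjusted p = 0.0536). Transcripts with at least 10 reads did not differ by the test, with 12521 ± 566 and 12530 ± 345 (SD, n = 6 each; exact permutation test, p = 0.970, adjusted p = 0.970).

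Single transcripts took much of that share, and those named here were chosen after their values were seen. LOC8275430, the most abundant in the mean of all 12 libraries, held 4.14% ± 0.616 of endosperm reads and 1.96% ± 0.495 of embryo reads (SD, n = 6 each), a log2 fold change of 1.34 ± 0.21 (SE; edgeR on 5 and 5 libraries, adjusted p = 0.000481). LOC8280732 held 3.61% ± 1.36 in endosperm and 0.252% ± 0.0836 in embryo (SD, n = 6 each), a log2 fold change of 4.15 ± 0.35 (SE; edgeR on 5 and 5 libraries, adjusted p = 2.22e-05). LOC8289755 differed most among these transcripts, at 1.28% ± 0.959 in endosperm against 0.00155% ± 0.000765 in embryo (SD, n = 6 each; edgeR on 5 and 5 libraries, log2 fold change 10.06 ± 1.12, SE, adjusted p = 8.03e-05). LOC8285550 held 1.67% ± 0.201 in endosperm and 1.43% ± 0.284 in embryo (SD, n = 6 each), and its log2 fold change of 0.39 ± 0.20 (SE) did not pass the test (edgeR on 5 and 5 libraries, adjusted p = 0.146).

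**Figure D4:**
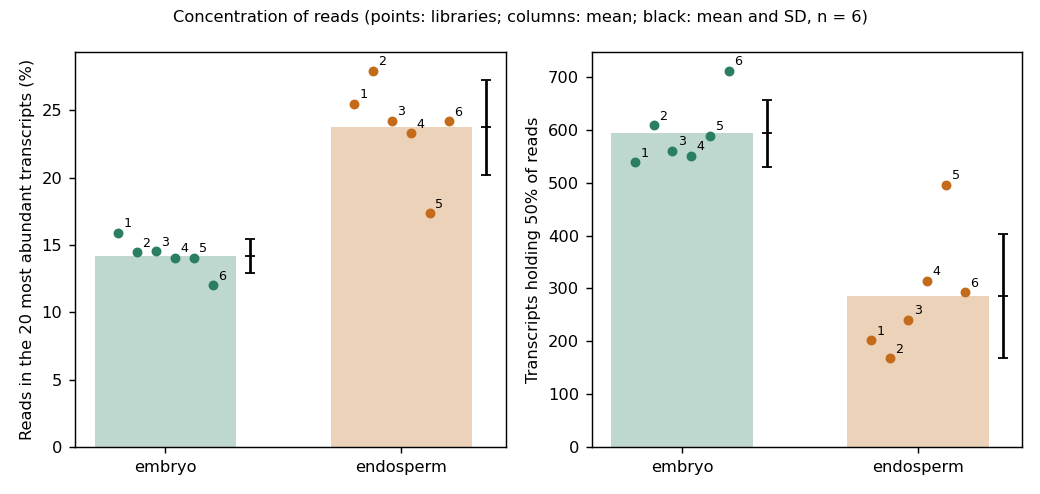
Percent of reads in the 20 most abundant transcripts of each library (left) and number of transcripts holding 50% of reads after thinning to 2675474 reads (right), with 1 point per library, columns for the mean and black bars for the mean and SD of 6 libraries. All endosperm libraries lie above all embryo libraries on the left and below them on the right, and endosperm library 5 is the endosperm library nearest to embryo in both.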

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

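The tests in this part on endosperm libraries 4 and 5 and on FAH12 were chosen after the results were seen. A single sample far from the other 5 of its tissue was found by Dixon's ratio in 7 of 26 groups of 6 values. Chance gives about 1.3 if the values are normally distributed, which was not tested. The groups come from the same 12 libraries and are not independent, so the 7 groups do not count separate anomalies. Of these 7, 4 concern endosperm library 5. It had 2675474 reads against a median of 7392300, 4.23% of reads on noncoding transcripts against 1.79%, 21.0% of reads on transcripts not matched to the newer reference against 12.9%, and 31.0 CPM of PPC3 against 2.01 CPM. Endosperm library 4 had 19.3 CPM of aap3 against a median of 6.32 CPM. Embryo library 2 had 15.1 CPM of LPAAT5 against a median of 11.6 CPM, and embryo library 4 had 2.77% of reads on noncoding transcripts against 2.47%. Endosperm library 5 also held 114 transcripts at least 4-fold above every other library, 57.9% of them unmatched against 29.6% of all transcripts, which took 6.51% of its reads, and without them its median correlation with the other endosperm libraries was still 0.0906 below that among those.

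Endosperm library 5 correlated with the other endosperm libraries at a median of 0.796, against 0.891 among those, and slightly better with the embryo libraries, at 0.807. Its low depth as the whole cause is argued against, because after all libraries were thinned to its depth the gap to the others was still 0.0885. An exchanged or wrong label is argued against as well, since all 6 embryo libraries correlated better with their own tissue, and transcripts restricted to endosperm stood in library 5 at a median of 46.1% of their endosperm level (lower quartile 27.7%), against an upper quartile of at most 3.60% in any embryo library. Embryo tissue carried into the library may contribute, but as the whole cause it is argued against. The 4.23% of reads on noncoding transcripts and 21.0% on unmatched transcripts lay above every other library of both tissues. The highest others were 2.77% in embryo library 4 and 18.2% in embryo library 6. A mixture of the tissues at the levels of the other libraries would give neither. Any contribution of embryo tissue cannot be told apart from a difference between seeds, which was not tested. Embryo-restricted transcripts stood at a median of 26.6% of their embryo level. Their quartiles were 2.14% and 127%, so tissue carried in at a single share does not account for all of them. The fall of endosperm-restricted transcripts needed a share of 53.9%, 27.3 percentage points more than that median. The bound of 10 points set for that test does not decide, since the same difference was 17.3, 7.21, -4.76 and 45.5 points in endosperm libraries 1, 2, 3 and 6, a comparison added after the values were seen, so 2 of these 4 exceeded it with embryo-restricted transcripts at 1.40% and 2.41%.

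Endosperm library 4 lay nearer to the embryo libraries than endosperm libraries 1, 2, 3 and 6, at a median correlation of 0.838 against 0.786. An exchange of labels with an embryo library is argued against, since all 6 embryo libraries correlated better with the other embryo libraries and library 4 correlated at 0.881 with endosperm libraries 1, 2, 3 and 6. Embryo tissue carried into it may be part of the cause: embryo-restricted transcripts stood at 10.02% of their embryo level, against 0.672% to 2.41% in endosperm libraries 1, 2, 3 and 6. Endosperm-restricted transcripts stood at 65.2%, so the 2 estimates of an embryo share differed by 24.8 percentage points. That exceeded the bound of 10 points, which by the written condition counts against embryo tissue carried in at a single share. The difference was larger than in endosperm libraries 1, 2 and 3 but smaller than the 45.5 points of endosperm library 6, a comparison added after the values were seen. Endosperm libraries 1 and 6 exceeded the bound too, so it does not decide. Carried-in embryo tissue cannot be told apart from a difference between seeds, which was not tested. Without library 4, 7266 transcripts were called instead of 6613 and 6240 were shared.

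FAH12 was lower in endosperm than in embryo of these mature seeds, against the direction of LPAT4. Earlier stages were not measured. The scaling of the libraries could account for the call. Of 4 other scalings, 3 kept the call, and upper quartile scaling ended it at a log2 fold change of -0.58 (edgeR, adjusted p = 0.0703, in a range of 0.0143 to 0.0777 over all alternatives that test for any difference). None turned the sign. These scalings moved the median log2 fold change of all transcripts only between -0.21 and 0.10, so they could hardly turn a value of -0.70. A larger difference of scale between the tissues was not tested, and the sign stays open to it. The written condition for scaling as the cause was changed, after these p-values had been seen, from a call that ends or turns to a sign that turns, and under the earlier wording the loss would have counted for scaling. Reads of the related FAD2 gene counted for FAH12 cannot be told apart either, because 0 transcripts were matched to FAD2, whose reads may stand under an unmatched accession. A difference between the tissues stays open.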

How the results depend on the processing

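The plan named all 12 libraries, but after the files had been seen the comparison was made on 10, and a fit on 12 with reads recovered for 2 was added as an alternative. That fit, also with the block, sums per gene, fits without a library, the share of the 20 most abundant transcripts in fewer libraries and all choices for noncoding transcripts, breadth, transcript usage, sister transcripts and neighbours were chosen after the data were seen; the other alternatives were planned. The count of 6613 called transcripts stayed within 1.5 times under 13 of 15 alternatives, including DESeq2 (7482, with 39 adjusted p left undefined), limma-voom (6967) and all 12 libraries (6052). It moved to 4352 (2136 higher in endosperm, 2216 in embryo) at an adjusted p of 0.01 and to 1882 (1049 and 833) when tested against a log2 fold change of 1, by construction. Leaving out a library gave 5849 (without embryo library 1) to 7266 (without endosperm library 4), 2924 to 3492 higher in endosperm and 2925 to 3774 in embryo. In the alternatives per transcript, 0 shared calls changed direction. The fits share most of their counts, so a transcript called in both could hardly do so.

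The label numbers were not taken to pair the tissues, which needed a correlation above 0.1 in every pair: deviations of libraries with the same number correlated at -0.002 to 0.170, above 0.1 in 3 of 6 pairs, and the own number was best in 2 of 6. With the replicate block 6113 transcripts were called (2907 and 3206), FAH12 (edgeR, adjusted p = 0.0521) and LPAAT5 (edgeR, adjusted p = 0.0536) lost their calls, and no other named transcript changed its call. With the block and all 12 libraries 5797 were called, FAH12 and LPAAT5 among them (edgeR, adjusted p = 0.0255 and 0.0456).

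Of 24 alternatives, LPAT4 kept its call in 24, GPC1 in 23, aap3 in 22, FAH12 in 15 and LPAAT5 in 12. CDPK2 reversed to -0.043 with library totals and lay between -0.079 (without endosperm library 4) and 0.51 (without embryo library 6) without 1 library; the cause was not tested. The difference in the share of the 20 most abundant transcripts was 9.58 points, 9.67 without endosperm library 4 and 10.9 without library 5. Tests of gene lists and of their shares, with their alternatives, were not run because no list had enough matched genes. Few simulated changes below a log2 fold of 2 were recovered. Only few transcripts were changed in that simulation, so the adjustment was stricter there than in the real comparison. The median size of a real call was 1.43 on the log2 scale for transcripts higher in endosperm and 1.21 for those higher in embryo.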

Other observations

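The noncoding set, transcript usage, sister transcripts and gene neighbours were chosen for testing only after the data had been seen.

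Transcripts with noncoding accessions, called noncoding here, were called as different between the tissues less often than coding ones. These accessions do not stand for noncoding genes only, since PDAT1-1 had both coding and noncoding accessions. Of 933 tested noncoding transcripts, 97 were higher in endosperm and 158 higher in embryo, 27.3% against 40.6% of the 15672 coding transcripts (edgeR, adjusted p at most 0.05). The direction leaned to embryo more than among coding transcripts, where 3170 and 3188 were called (Fisher's exact test across transcripts, which are not independent, p = 0.000258), and more noncoding transcripts were higher in embryo under every scaling tried, by 133 to 118 with upper quartile scaling. As a set they did not stand apart from other transcripts in camera (p = 0.135, or p = 0.101 with an estimated correlation), with a median log2 fold change of -0.27. Noncoding transcripts held 2.49% ± 0.150 of embryo reads and 2.14% ± 1.06 of endosperm reads (SD, n = 6 each; exact permutation test, p = 0.524, adjusted p = 0.589), and without endosperm library 5 the endosperm share was 1.72% ± 0.291 (SD, n = 5; exact permutation test, p = 0.00433, adjusted p = 0.00649).

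Estimated transcript usage differed between the tissues in some genes. Salmon's sharing of reads between transcripts of a gene could add to such differences and was not tested. LOC8281720, chosen after its values were seen, had 1 transcript at 9.38 ± 0.852 CPM in embryo with 0 reads in endosperm and another at 0.0181 ± 0.0405 CPM in embryo and 2.73 ± 0.904 CPM in endosperm (SD, n = 5 each), while its main transcript was 48.4 ± 4.28 CPM and 24.6 ± 5.84 CPM. In LOC8277715, likewise chosen, a transcript at 2.92 ± 1.75 CPM in embryo had 0 reads in endosperm, and another rose from 18.2 ± 2.61 CPM to 33.4 ± 3.41 CPM (SD, n = 5 each). Of 1949 genes with at least 2 tested transcripts, 137 were called for usage by diffSpliceDGE of edgeR (50 by its Simes test, 391 at an unadjusted p of 0.05). The count was 60 with all 12 libraries and 291 without endosperm library 4, and otherwise 97 to 137 without 1 library.

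Splits of the 10 libraries other than by tissue gave almost no calls. Each of them put both tissues in both groups, which widened the spread within groups, so few calls could arise. The comparison therefore cannot tell a tissue difference from anything else that went with tissue. Of 100 drawn splits out of 126, 1, the real one, gave as many as 6613 transcripts, and the highest other split gave 2. For transcript usage, again 1 of 100 gave as many as 137 genes, and the highest other split gave 10.

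A hypothesis was that noncoding transcripts are called less often because they are less abundant. The 255 calls lay below all 10000 sets of coding transcripts matched on abundance, which held 310 on average and at least 258 (permutation test, p = 0.0001, the smallest these sets can give). Abundance may therefore account for only part of the gap to coding transcripts, and the rest was not explained. Salmon's sharing of reads between noncoding and coding transcripts of a gene could add to the gap and was not tested.

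Another hypothesis was that sister transcripts of a gene are called in opposite directions as often as unrelated ones. Opposite calls occurred in 27 genes, 25 of them also called for usage, against 124 on average and at least 91 when transcripts were dealt at random over genes (permutation test, p = 0.0001, the smallest these deals can give). The count was 15 with all 12 libraries and 45 without endosperm library 4. Sister transcripts may move together, though Salmon's sharing of reads between them could add to this and was not tested.

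A last hypothesis was that genes called in the same direction lie side by side. Of 5002 adjacent pairs among 10062 genes, 604 were called in the same direction, against 547 on average in 10000 random placements (permutation test, p = 0.00310), 351 of them higher in endosperm and 253 in embryo. The condition written before this test counted a number within the random placements as random placement, and only a number above the highest, 621, against it. The observed number lay within them, so under that condition random placement was not excluded. Few placements reached it, and under other settings of the calls the p-value was 0.0010 to 0.010 (permutation test). The condition and the p-values thus point different ways, and the question stays undecided. The longest run held 5 genes higher in endosperm, LOC8271752 to LOC8271757, with log2 fold changes of 0.45 to 1.47. Neighbouring copies of a gene family that share reads could give such runs and were not tested.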
